A study of Mus musculus with 2 samples.

How the data were processed

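H3K9ac, the acetylation of lysine 9 of histone H3, was profiled by chromatin immunoprecipitation and sequencing in midbrain tissue of mouse embryos at embryonic day 15.5. The 2 samples were biological replicates of a single group, of strain B6NCrl, each a pool of male and female embryos. Replicate 1 came from 78 embryos and replicate 2 from 62 embryos. The labels give a size range of 300 to 500 for both libraries without stating its unit, and both samples carry the same donor label.

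The deposited data were 4 peak lists on mm10, in which each peak has a position and 3 measures of strength. Per the deposited file descriptions, 1 list was called from the filtered alignments of replicate 1 with a control alignment, and another from those of replicate 2 with a control alignment. A pooled list was called from both replicates and their controls together, and a replicated list was derived from the pooled list and the list of each replicate. Every replicated peak was also present in the pooled list with the same values, as tested on the lists. The enrichment measure deposited with each peak was a signal value against the control, in the column order of the narrowPeak format, and its scale was not stated. The authors also deposited for each peak the −log10 p and the −log10 q of the peak caller, and the −log10 p was above 2 in every list. The aligner, the peak caller, its thresholds and the rule that makes a peak replicated were not given in the sources used here. Read counts and alignments were not analysed here, so the depth of each library is unknown. The intervals given on shares of peaks or genes therefore cover counting error over peaks or genes and not sequencing error. Signal values and peak counts were not rescaled between replicates, and their differences between the replicate lists were not read as differences in acetylation.

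The reference was the GRCm38 genome with the GENCODE M21 annotation, which is the build named for the peak lists, and 0 peaks and 0 annotated genes lay past a chromosome end. Coordinates are 1-based on mm10. Peaks on the main chromosomes were used for location, and the 9 replicated peaks on scaffolds were left out of it. A gene was called marked where a peak overlapped, by at least 1 bp, the interval of 1 kb on either side of any transcript start of 1 of the 21938 protein-coding genes. A peak in such an interval was a promoter peak. The promoter domain of a gene was the widest stretch over its promoter interval after replicated peaks had been merged across gaps of up to 1 kb. The promoter signal was the highest signal value of a peak in that interval. Distal peaks lay over 2 kb from every transcript start of any gene. They were assigned to the protein-coding gene with the nearest transcript start within 100 kb. The observed over expected CpG ratio of a promoter was taken within 500 bp of the 5′ end of the gene, which may not be the marked start.

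A set of 20 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. It comprised midbrain dopaminergic genes, midbrain regional regulators, forebrain regulators, Hox genes, general neuronal genes, neural progenitor genes, transmitter identity genes, oligodendrocyte lineage genes, astrocyte genes, microglia and immune genes, endothelial and mural genes, erythroid genes, meningeal and mesenchymal genes, liver genes, heart and skeletal muscle genes, germline genes, housekeeping genes, cell cycle genes, immediate early genes and odorant receptors. A single listed gene, Ahsp of the erythroid list, was absent from the annotation. Some genes stand in more than 1 list, such as Tal1 among the regional regulators and the erythroid genes. The text could name any member of these lists. Examples were the marked members with the widest promoter domains and the unmarked members in list order. It could also name the 10 genes with the widest domain, the 10 with the highest promoter signal, the 10 with the most distal peaks, the 5 distal peaks with the highest signal, and the 5 genes with the widest domain among those marked in 1 replicate list alone, for each replicate. Genes named outside this rule are said to have been chosen after their values were seen.

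With 2 samples in 1 group there was no test between groups. Overlap between the replicate lists was compared with 100 random placements of the peaks on the same chromosomes. Spearman correlations were taken across peaks, which are not independent replicates, and have no p-value. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test of promoter peaks. Median domain width and median promoter signal were compared with 100000 random lists of marked genes of the same size by a two-sided permutation test. This test was run on the 13 lists with at least 5 marked genes. The mean number of distal peaks per gene was compared with 100000 random lists matched in 20 bins on territory, the stretch of genome from which a gene could be assigned distal peaks. Genes marked in 1 replicate list alone were tested by a two-sided Fisher's exact test over the 17 lists with at least 5 genes marked in either replicate, which compares 2 samples and not conditions. Adjusted p-values are Benjamini-Hochberg values over the lists of each test, with a threshold of 0.05. The smallest p that the permutations can give is 2e-05, and 0.0002 for the 10000 draws used in alternatives. Genes of a list, and neighbouring genes, are not independent of one another, so the p-values describe how a list stands among genes and not how it would vary between animals.

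The alternatives fixed beforehand were the list of either replicate, the pooled list, the 50% of peaks with the higher signal, equal lists of the top 20000 peaks, and promoter intervals of 0.5 kb and 2 kb. Others were the gene's 5′ end as the only start, no merging or merging across 3 kb, a distal limit of 5 kb, an assignment limit of 50 kb, an overlap of 50% of the peak, and random lists matched on promoter CpG in 10 bins. Alternatives added after seeing the data left out genes that share a promoter, matched the random lists for promoter signal on CpG or those for width on the number of transcript starts, or took the 50% of each replicate list with the higher signal for the replicate comparison.

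Computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data before use. With values simulated over the 21938 protein-coding genes, the Fisher, median and mean tests each recovered 100 of 100 lists with a planted difference. They called 3, 6 and 3 of 280 lists with none. The planted differences were large and the genes were simulated independently. The recovery therefore does not give the power for smaller differences or for related genes. The overlap step returned 0 wrong or missing pairs among 1217 simulated overlaps.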

Results

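H3K9ac, a histone mark of active promoters and enhancers, was mapped in the midbrain of mouse embryos at embryonic day 15.5. The group held 2 biological replicates, pools of 78 embryos (replicate 1) and 62 embryos (replicate 2). The peak list of replicate 1 held 40662 peaks over 24.7 Mb, and that of replicate 2 held 63385 peaks over 35.8 Mb. The replicated list, on which the values below rest unless another list is named, held 27617 peaks over 29.8 Mb, with a median width of 838 bp and a median signal value of 6.10. Of these, 24434 (88.5%) overlapped peaks of both replicate lists, 2623 of that of replicate 2 alone, 491 of that of replicate 1 alone and 69 of neither, and the rule that makes a peak replicated is not known. Sequencing depth is unknown, since peak lists alone were analysed. Values of the replicated list are single values without a replicate error, and each replicate's own value is given where it bears on the result.

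The first comparison, between the replicates, asked which peaks and genes the 2 pools of tissue shared. Promoters of neuronal genes such as Tubb3, a neuronal tubulin, Map2, a dendritic microtubule protein, and Snap25, part of the synaptic release machinery, were marked in both. In all, 13659 protein-coding genes had a promoter peak in both lists, 149 in the list of replicate 1 alone and 757 in that of replicate 2 alone. The genes with the widest domains in the list of replicate 1 alone were Muc1, an epithelial mucin, with 4804 bp, Gckr, the glucokinase regulator, with 3303 bp, Exoc3l with 2903 bp, Gm20479 with 1830 bp and Tmem235 with 1323 bp. Those in the list of replicate 2 alone were Tmem102 with 5456 bp, Gpsm3 with 5105 bp, Slc35g3 with 4943 bp, Iqcn with 4819 bp and Ovol3 with 4701 bp. In 9 of these 10 genes, all but Tmem235, that domain was also the one of a neighbouring gene marked in both replicates, such as Polr2a beside Slc35g3, Pbx2 beside Gpsm3, Fgf11 beside Tmem102 and Jund beside Iqcn, neighbours named after the values were seen. It thus reached into the promoter interval of the named gene in 1 replicate only. Over all genes marked in 1 replicate this held for 5 of 149 and 23 of 757, and for none of those in the 20 gene lists.

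Of the replicate 1 peaks, 75.2% (30590 of 40662, Wilson 95% interval 74.8 to 75.6%) overlapped a replicate 2 peak by at least 1 bp, against 3.10% on average and at most 3.43% after random placement. Of the replicate 2 peaks, 42.0% (26619 of 63385, 41.6 to 42.4%) overlapped a replicate 1 peak, against 2.00% on average and at most 2.16%. The overlap rose with peak strength. In the decile of peaks with the lowest −log10 p it was 38.8% for replicate 1 and 5.93% for replicate 2, and in the decile with the highest it was 100% for both. When the 20000 strongest peaks of each list were taken, the shares were 93.3% and 84.5%. Across the 24434 replicated peaks found in both replicate lists, the Spearman correlation of the signal values was 0.84. It was 0.58 over the 7232 of them away from promoters.

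**Figure D1:**
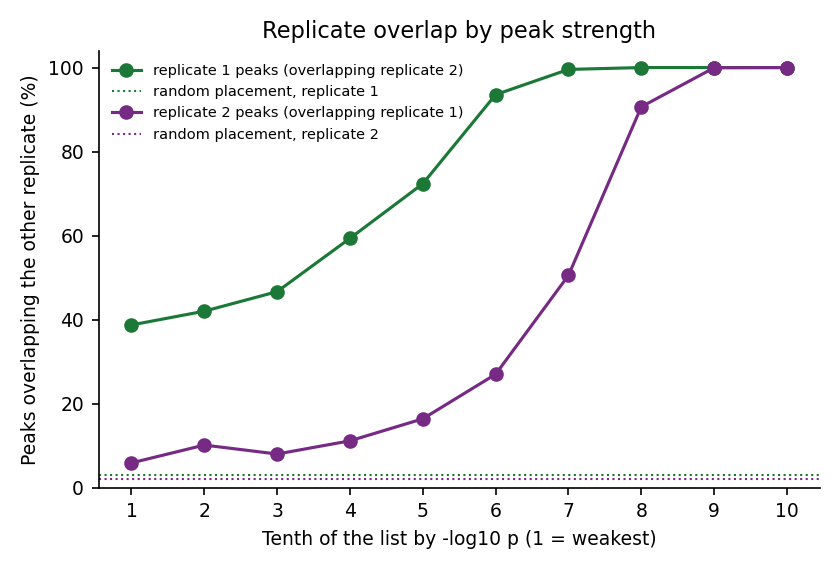
Share of peaks of each replicate that overlapped a peak of the other replicate (y axis, %), by deciles of the list ordered by −log10 p from weakest to strongest (x axis). The share reached 100% in the strongest decile of both lists and was 38.8% (replicate 1) and 5.93% (replicate 2) in the weakest.

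The midbrain regional regulators Pax3, Helt and Nkx6-1, the dopaminergic genes Foxa2 and Corin and the progenitor gene Neurog1 were marked in replicate 2 alone. So were some genes of glia, of other tissues or of other parts of the nervous system. They included the microglial genes C1qb, a complement subunit, Csf1r, the receptor for colony stimulating factor, Aif1 and Tmem119, and the meningeal and mesenchymal genes Col1a1, a fibrillar collagen, and Aldh1a2, a retinoic acid synthesising enzyme. Others were the mesenchymal regulators Prrx1 and Tbx18, the heart genes Nkx2-5, Nppa and Tnni3, the Hox genes Hoxa1, Hoxb7, Hoxd1 and Hoxd8, and Olig2, Sox10 and Cspg4 of the oligodendrocyte lineage. The odorant receptors among them, Olfr270, Olfr279, Olfr412, Olfr1414 and Olfr1427, had replicate 2 domains of 175 to 248 bp. Those of other lists were narrow too, with 236 bp at Sox10, 279 bp at Olig2 and 531 bp at Cspg4. Over all members marked in replicate 2, the median was 217 bp for microglia and immune, 355 bp for Hox and 656 bp for heart and skeletal muscle genes. By two-sided Fisher's exact tests over genes marked in either replicate, 6 of the 17 lists tested had a higher share than the genes outside the list, of which 5.17 to 5.20% were in replicate 2 alone. By this exact test these were the odorant receptors (5 of 6 genes, adjusted p = 3.66e-05), the Hox genes (4 of 5, adjusted p = 0.000197), the microglia and immune genes (4 of 5, adjusted p = 0.000197), the meningeal and mesenchymal genes (4 of 9, adjusted p = 0.00314), the heart and skeletal muscle genes (3 of 5, adjusted p = 0.00439) and the oligodendrocyte lineage genes (3 of 11, adjusted p = 0.0478). Lists with few genes marked in replicate 1 are favoured by that comparison. Among genes unmarked in replicate 1, in a test added after the data were seen, no list passed the threshold with a higher share marked in replicate 2 than CpG-matched lists, and the odorant receptors passed with a lower one (0.458% against 3.84%, permutation adjusted p = 0.00024). There the Hox genes had 10.5% against 29.5% (permutation adjusted p = 0.0506), the microglia and immune genes 26.7% against 8.29% and the meningeal and mesenchymal genes 44.4% against 19.4% (permutation adjusted p = 0.198 and 0.274). No list was over-represented in replicate 1 alone after adjustment by the same exact test. The forebrain regulators Foxg1 and Gsx2 (2 of 17 genes, unadjusted exact p = 0.0128) came closest. Of the 6 calls that of the oligodendrocyte lineage ended with a promoter interval of 0.5 kb (2 of 10 genes, exact adjusted p = 0.208) and of 2 kb (3 of 12, exact adjusted p = 0.0575), and the other 5 held with 2 kb. With 0.5 kb that of the meningeal and mesenchymal genes held, and the endothelial and mural genes passed too (3 of 8, exact adjusted p = 0.0340). The other 4 of the 6 lists had too few marked genes for the test. In replicate 2 alone were 3 of 4 Hox, 4 of 4 microglia and immune, 3 of 4 heart and skeletal muscle and 2 of 3 odorant receptor genes. With the 50% of each list of higher signal, an alternative added after the data were seen, the same 4 lists were too small. There 7 lists passed, led by the meningeal and mesenchymal (7 of 8 genes, exact adjusted p = 2.88e-06) and endothelial and mural genes (5 of 8, 0.00124). The others were the cell cycle (7 of 20, 0.00376), dopaminergic (5 of 14, 0.0144), forebrain (4 of 10, 0.0182), transmitter (4 of 12, 0.0301) and oligodendrocyte lineage genes (3 of 7, 0.0301). With the 20000 strongest peaks of each list, in which the oligodendrocyte call ended (2 of 6 genes, exact adjusted p = 0.0908) and the other 5 lists were too small, 1 list was over-represented in replicate 2 alone, the cell cycle genes (27.8%, Pcna, E2f1, Mki67, Cdk1 and Top2a, exact adjusted p = 0.00762), and 2 lists in replicate 1 alone, the midbrain dopaminergic genes (18.2%, Foxa1 and Slc6a3) and the transmitter identity genes (20%, Slc17a7 and Slc6a2), each at an exact adjusted p of 0.0449. The dopaminergic share in replicate 2 alone was also 18.2% there (exact adjusted p = 0.174). Of the lists too small there, the meningeal and mesenchymal genes had 4 of 4 in replicate 2 alone, and the others had none.

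The second comparison asked where in the genome the mark lay. Basp1, a growth cone protein of developing axons, had the highest promoter signal, 34.6. It was followed by Srsf6, a splicing factor, with 31.6 and Marcks, an actin-binding substrate of protein kinase C, with 31.0. The remaining genes of the 10 with the highest signal were Fnbp1l, Sp3, Ssb, Mdm2, Sptan1, Tra2a and Ptpn12, between 27.4 and 29.3. Basp1 (ENSMUSG00000045763.8) lies on chromosome 15 at 25363277 to 25413764, with its domain at 25409072 to 25418822 over the start of the gene. In the replicate lists its signal was 29.96 (replicate 1) and 30.6 (replicate 2).

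Of the 27608 replicated peaks on the main chromosomes, 65.7% (18139) were promoter peaks of protein-coding genes, against a mean of 5.87% after random placement. The share was 55.6% in the list of replicate 1 and 38.9% in that of replicate 2. Introns of protein-coding genes held 12.6% (random 29.4%), exons 3.75% (random 6.86%), promoters of other genes 4.78% (random 3.42%) and intergenic sequence, here all else outside protein-coding genes, 13.2% (random 54.5%). The median signal was 9.13 at promoters of protein-coding genes and between 3.32 and 4.67 in the other classes. Of the 21938 protein-coding genes, 13793 (62.9%) were marked, and the number was 13808 with the list of replicate 1 and 14416 with that of replicate 2. The marked share followed promoter CpG. It was 11.4% of genes with an observed over expected ratio below 0.25, 48.4% from 0.25 to 0.5, 92.0% from 0.5 to 0.75 and 98.1% above 0.75.

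Outside promoters, the genes with the most distal peaks were led by a pair of corepressor genes. Gse1, a subunit of a corepressor complex, had 34 distal peaks, 33 of them within its own body, and Bcor, the X-linked corepressor of BCL6, had 18, of which 14 lay within the gene. Irf2bpl had 17, Ahdc1 15, Ebf3, a transcription factor of differentiating neurons, 15, and Celf4, a neuronal RNA-binding protein, 14. Cstad and Trim27 had 12 each, none within the gene, and Zfhx3 and Zmiz1 had 11 each. Gse1 (ENSMUSG00000031822.20) lies on chromosome 8 at 120228456 to 120581390. The distal peaks with the highest signal were an intergenic peak on chromosome 8 at 69716130 to 69716926 (signal 24.5, 5804 bp from the nearest start, of Zfp869), and one on chromosome 12 at 8640761 to 8641760 (23.6, 32873 bp from Pum2). A peak of 4919 bp at 27335199 to 27340117 on the same chromosome (22.9) lay in the exon of Sox11, a regulator of neuronal differentiation with a long single exon. The other 2 also lay outside protein-coding genes, at 96709906 to 96710714 on chromosome 15 (18.5, nearest to Slc38a2) and at 46304866 to 46305754 on chromosome 4 (18.4, nearest to Foxe1 and overlapping the non-coding gene Gm12446). In total 6551 replicated peaks (23.7%) were distal, 5711 of them were assigned to a gene, and 3357 genes had at least 1. Assignment to the nearest start does not show which gene a peak acts on.

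The third comparison asked which groups of genes carried a promoter peak. General neuronal, neural progenitor and cell cycle genes were marked throughout or nearly so, while those of liver, blood, muscle, germ cells and the posterior body axis were mostly unmarked. All 20 general neuronal genes were marked, among them Myt1l, a regulator of neuronal identity, Celf4 and the RNA-binding protein gene Elavl2. So were 18 of 18 housekeeping genes, such as Actb and Polr2a, and 13 of 13 immediate early genes, such as Egr1, Junb and Ier2, which respond rapidly to cell stimulation. In the neural progenitor list 19 of 20 were marked, with Msi1 and the proneural gene Ascl1 among them and the proneural gene Neurog1 the exception. In the cell cycle list 19 of 20 were marked, Ccnb2 being the exception. Of the midbrain regional regulators, the transcription factors that pattern the midbrain, 19 of 22 were marked, with Lhx5, Lhx1 and Otx2 among them. The 3 unmarked ones were Pax3, Helt and Nkx6-1, each of which had a promoter peak in the list of replicate 2.

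These 6 lists had a higher marked share than other protein-coding genes (62.8 to 62.9%) by two-sided Fisher's exact tests. The adjusted p was 0.000359 for general neuronal genes, 0.000897 for housekeeping genes, 0.00367 for neural progenitor and for cell cycle genes, 0.00549 for immediate early genes and 0.0393 for midbrain regional regulators. Against random lists with the same promoter CpG, 1 of the 6 calls held, that of the general neuronal genes (100% against 72.7%, permutation adjusted p = 0.00200). With the 50% of replicated peaks of higher signal, 3 lists were higher (general neuronal, housekeeping and neural progenitor genes), the call of the immediate early genes ended (61.5%, exact adjusted p = 0.623), and the shares of the regional regulators (31.8%, exact adjusted p = 0.0633) and cell cycle genes (50%, 0.825) fell below those of other genes. Against CpG-matched lists the regional regulators also turned direction (86.4% against 93.2%, permutation adjusted p = 0.547), and with the 5′ end of the gene as the only start their call also ended (77.3%, exact adjusted p = 0.181).

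Hox genes, which specify the hindbrain and spinal cord but not the midbrain, were marked in 2 of 39 cases, Hoxa1 and Hoxa7 (odds ratio 0.0318, exact adjusted p = 3.45e-13), although their promoters are rich in CpG (median observed over expected ratio 0.679). Their share was 5.13% against 86.3% in lists matched on CpG (permutation adjusted p = 0.00133). Of the 1093 odorant receptors, sensory genes of the nasal epithelium, 1 was marked, Olfr94 (odds ratio 0.000468 by Fisher's exact test, with a p too small to be represented). None of the 15 liver genes was marked, Alb, Afp and Apoa1 being the first of the list (exact adjusted p = 2.32e-06). Cd68, a lysosomal protein gene, was the marked member of the 16 microglia and immune genes (exact adjusted p = 1.82e-05). Gdf9 and Dazl were marked among the 16 germline genes (exact adjusted p = 0.000193). Among 15 heart and skeletal muscle genes, Myh7, Ckm and Nppa were marked (exact adjusted p = 0.00222). Among 13 erythroid genes, Tal1, Klf1 and Gypa were marked (exact adjusted p = 0.0109). Tal1 is also a midbrain regional regulator. Of these 7 lists with a lower share, the Hox genes, germline genes and odorant receptors passed against CpG-matched lists, and the liver (permutation adjusted p = 0.0640), microglia, heart and erythroid lists did not. With the list of replicate 2 the counts rose to 5 Hox, 5 microglia and immune, 5 heart and skeletal muscle, 2 liver and 6 odorant receptor genes, and with that of replicate 1 they were 1, 1, 2, 0 and 1, all still lower by the exact test. A promoter interval of 2 kb also ended the call of the heart and skeletal muscle genes (40%, exact adjusted p = 0.0987).

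The other 7 lists did not pass the exact test. In the midbrain dopaminergic list, genes of the neurons that make dopamine, 12 of 18 were marked. Wnt5a, En2, En1 and Nr4a2 had the widest domains, and Th, the rate-limiting enzyme of dopamine synthesis, had no promoter peak in the list of either replicate. Among forebrain regulators 11 of 20 were marked, led by Bcl11b, Lhx2 and Emx2, while Foxg1, Tbr1, Nkx2-1, Dlx1 and Dlx2 were not. In the list of each replicate 15 of 20 were marked, Dlx1 and Nkx2-1 in both lists, Foxg1 in that of replicate 1 and Dlx2 in that of replicate 2. Against CpG-matched lists their share was lower (55% against 77.4%, permutation adjusted p = 0.0152), but in the pooled list it was higher than that of other genes (90%, exact adjusted p = 0.0438), so that the direction turned with the peak list, as it did without passing in the list of each replicate (75%, exact adjusted p = 0.419 and 0.604). The counts were 12 of 17 for transmitter identity genes, 7 of 15 for the oligodendrocyte lineage, 8 of 13 for astrocyte genes, 9 of 16 for endothelial and mural genes and 7 of 14 for meningeal and mesenchymal genes. Those of the forebrain regulators, oligodendrocyte lineage, endothelial and mural, and meningeal and mesenchymal lists became lower calls with the 50% of replicated peaks of higher signal, in which 20%, 13.3%, 6.25% and 0% of the genes were marked (exact adjusted p = 0.00460 for the first 2, 0.000347 and 7.60e-05).

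**Figure D2:**
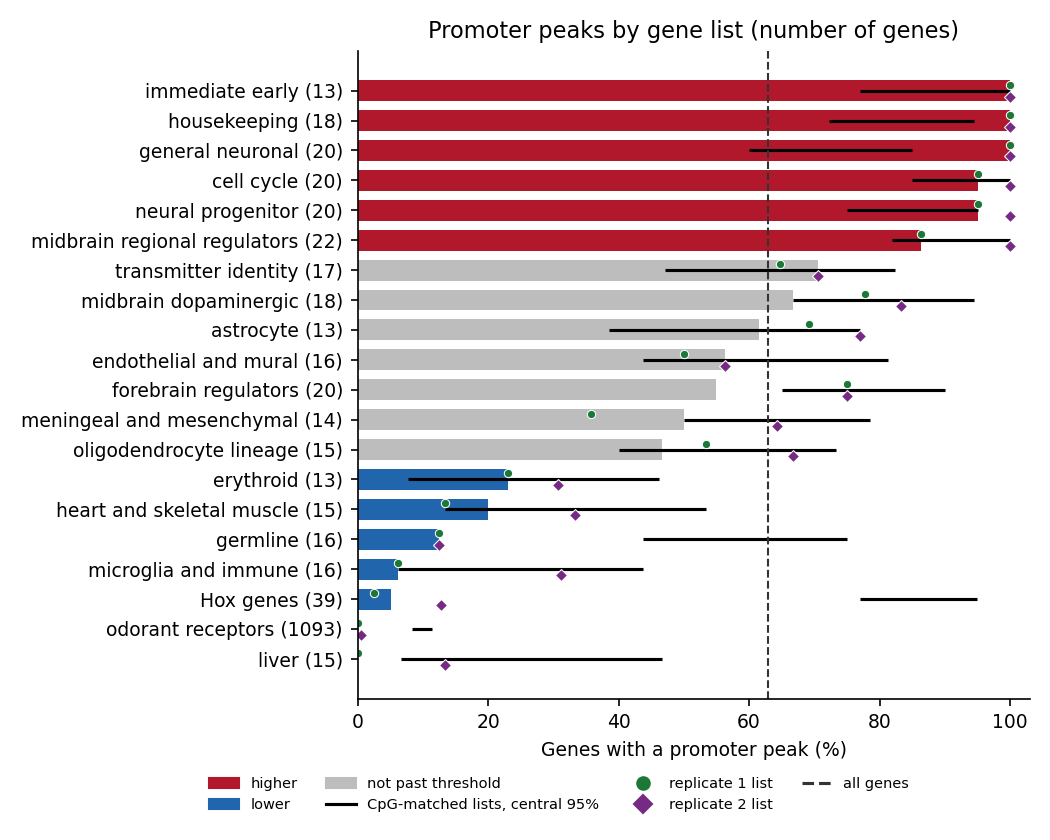
Percentage of genes with a promoter peak in each of the 20 lists (x axis from 0; number of genes in parentheses). Bars show the replicated list, coloured where Fisher's exact test passed, dots and diamonds show the lists of replicates 1 and 2, black lines the central 95% of CpG-matched random lists, and the dashed line all protein-coding genes (62.9%); Hox genes (5.13%) and germline genes (12.5%) lie far below their matched lists.

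The fourth comparison asked how far the mark spread around marked promoters. Pou3f3, a neural POU factor, had the widest, 21536 bp, followed by Zfhx3 with 19613 bp, Mn1 with 18298 bp, the LIM homeobox genes Lhx9 with 17996 bp and Lhx5 with 16632 bp, and Ebf3 with 16495 bp. Bahcc1, Pou3f2, Nr2f1 and Tnrc18 had 14283 to 15590 bp. The median over marked genes was 1815 bp. Pou3f3 (ENSMUSG00000045515.3) lies on chromosome 1 at 42695768 to 42703176, with its domain at 42684045 to 42705580, and the domain was 11743 bp in replicate 1 and 22131 bp in replicate 2. That of Ebf3 was 7530 and 16491 bp, while Zfhx3 had 19490 and 19704 bp.

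Midbrain regional regulators were the widest of the 13 lists tested, with a median of 7042 bp over 19 marked genes. Among them Lhx1 had 14023 bp, Otx2, which marks the fore- and midbrain against the hindbrain, 13823 bp, Meis2 12969 bp, Tfap2b 9607 bp and Gata3, a regulator of midbrain GABAergic neurons, 8229 bp. General neuronal genes had a median of 3852.5 bp, led by Myt1l with 14051 bp and Celf4 with 9219 bp. The medians were 3561 bp for immediate early genes, 3038 bp for neural progenitor genes, where Msi1 had 9220 bp, and 2543.5 bp for housekeeping genes. All 5 lists were wider than random lists of marked genes by the two-sided permutation test. The adjusted p was 0.00013 for the first 2 lists, from the smallest p that the permutations can give, and 0.000953, 0.000975 and 0.0291 for the others. Without merging of peaks the calls of the regional regulators (1897 bp, permutation adjusted p = 0.0872), immediate early genes (1753 bp, 0.273) and housekeeping genes (1794 bp, 0.163) ended, so these widths reflect runs of neighbouring peaks. With the 50% of replicated peaks of higher signal the call of the immediate early genes ended too (1858 bp, permutation adjusted p = 0.907).

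Transmitter identity genes were split. Slc17a6, the vesicular glutamate transporter of midbrain and thalamus, had 13027 bp, and the GABAergic genes Gad2, Slc32a1 and Gad1 had 9978, 9634 and 7939 bp. The cholinergic genes Chat and Slc18a3, which share a promoter domain, had 604 bp, and Slc6a2, Slc17a7 and Fev had 398 to 441 bp. The median of the 12 was 966 bp, below that of random lists (permutation adjusted p = 0.00744), but with peaks merged across 3 kb it was 2564 bp and with the 50% of peaks of higher signal 5425 bp, above random lists (permutation adjusted p = 0.143 and 0.000533), so that the direction of the median turned. The midbrain dopaminergic list (median 1097.5 bp, adjusted p = 0.0269), the forebrain regulators (1084 bp, 0.0309) and the endothelial and mural genes (898 bp, 0.0136) were also narrower by the permutation test. The first of these included Wnt5a with 7507 bp, En2 with 6592 bp and En1 with 5762 bp beside Slc6a3, the dopamine transporter, with 597 bp. The narrow calls rested in part on the peak list, on merging and on the background. Against CpG-matched lists those of the forebrain regulators (permutation adjusted p = 0.0551) and endothelial genes (0.0511) ended and the cell cycle genes passed as narrower (0.0243), and against lists matched on transcript starts those of the dopaminergic genes (0.0839) and forebrain regulators (0.0565) ended. With the list of replicate 2 alone those of the transmitter (1292 bp, permutation adjusted p = 0.0991), dopaminergic (1396 bp, 0.146) and endothelial genes (1731 bp, 0.699) ended, and with gaps of 3 kb the forebrain regulators had 2750 bp (permutation adjusted p = 0.108). The other 4 lists tested did not pass: 1708.5 bp for astrocyte, 1346 bp for cell cycle, 1249 bp for meningeal and mesenchymal and 1047 bp for oligodendrocyte lineage genes (permutation adjusted p = 0.777, 0.0730, 0.171 and 0.0648). With the list of 1 replicate alone, permutation calls of narrow domains were gained by oligodendrocyte lineage genes (749 bp, adjusted p = 0.00340, with replicate 2; 511.5 bp, 0.00371, with replicate 1), meningeal and mesenchymal genes (824 bp, 0.0133, with replicate 2) and cell cycle genes (1022 bp, 0.0268, with replicate 1). The Hox, microglia and immune, heart and skeletal muscle, and odorant receptor lists reached 5 marked genes with replicate 2 alone and were then narrower too (213 to 656 bp, permutation adjusted p = 0.00113 to 0.0201).

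**Figure D3:**
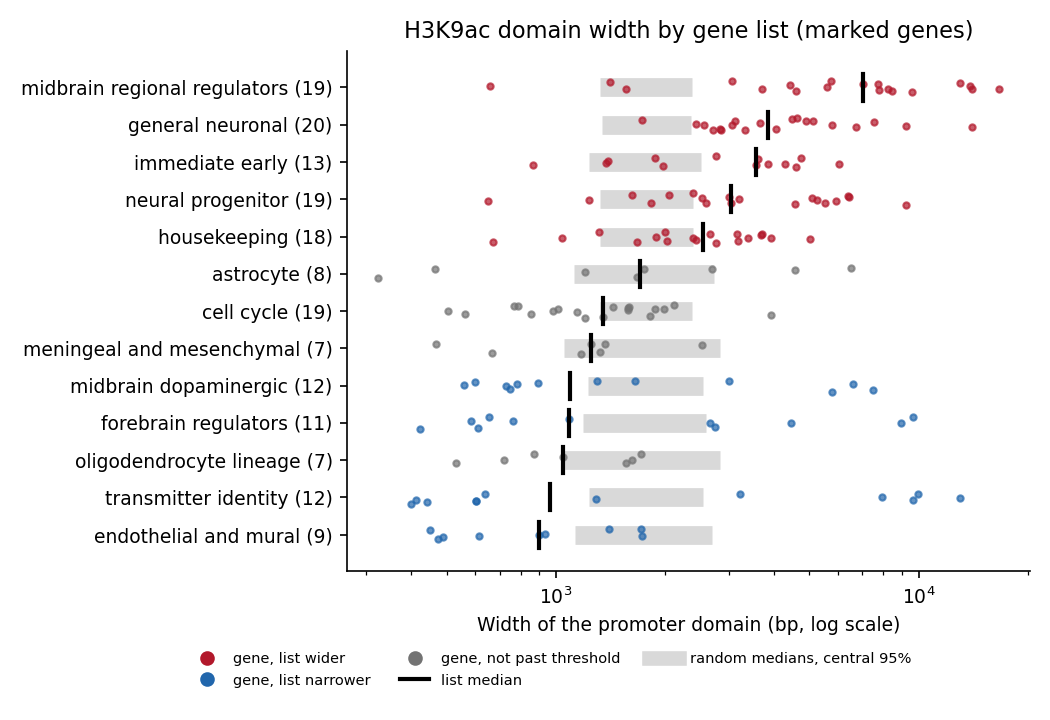
Width of the promoter domain of each marked gene (points, bp, log axis) in the 13 lists with at least 5 marked genes, with the list median (black tick) and the central 95% of medians of random lists (grey). The median of the midbrain regional regulators, 7042 bp, lies furthest above its random range of 1320 to 2378 bp.

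Height did not follow width in every list. Promoter signal was higher than in random lists of marked genes for general neuronal genes (median 14.8) and housekeeping genes (14.9), such as Celf4 with 21.5 and Actb with 22.6 (permutation adjusted p = 0.0177 each, against a random median of 11.6). The midbrain regional regulators, the widest list, had a median signal of 5.41 (permutation adjusted p = 0.00026), with 5.45 at Otx2 and 4.96 at Gata3. The other 10 lists tested were lower as well. Their medians were 3.36 for meningeal and mesenchymal genes, 3.94 for forebrain regulators, 4.35 for endothelial and mural, 4.56 for oligodendrocyte lineage, 5.79 for transmitter identity, 6.05 for astrocyte, 6.16 for dopaminergic, 6.25 for cell cycle, 6.90 for immediate early and 8.61 for neural progenitor genes. Their permutation adjusted p ran from 0.00026 to 0.0499. The higher call of the general neuronal genes ended with the list of replicate 1 alone (10.4, permutation adjusted p = 0.153), the lower call of the immediate early genes ended with that of replicate 2 alone (8.20, permutation adjusted p = 0.0662), and with the 50% of replicated peaks of higher signal both higher calls ended (permutation adjusted p = 0.0647 each).

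The fifth comparison asked which genes gathered distal peaks. Immediate early genes had 1.85 distal peaks per gene against 0.244 in random lists matched on territory (permutation adjusted p = 0.0008), and midbrain regional regulators had 2.32 against 0.452 (permutation adjusted p = 0.00147). Forebrain regulators (1.2 against 0.334) and neural progenitor genes (1.55 against 0.410) were higher too, at permutation adjusted p of 0.0192 and 0.0200. Odorant receptors were lower, with 0.0174 against 0.130 (permutation adjusted p = 0.0004). The other 15 lists did not pass, the general neuronal genes (1.9 against 0.572, permutation adjusted p = 0.0562) and the transmitter identity genes (0.941 against 0.283, permutation adjusted p = 0.0723) coming closest. Both of these passed with the list of replicate 1 alone (3.25 and 1.59 peaks per gene, permutation adjusted p = 0.0344 and 0.0373) and with that of replicate 2 alone (7.15 and 3.41, permutation adjusted p = 0.00600 and 0.0144). The call of the forebrain regulators ended with replicate 2 alone (3.0, permutation adjusted p = 0.0623) and that of the neural progenitor genes with replicate 1 alone (1.9, permutation adjusted p = 0.0731). Distal peaks were counted without merging, and those within promoter domains were not left out. A wide domain can therefore also add to this count. With a distal limit of 5 kb the call of the immediate early genes was the 1 higher call left. None was left with the 50% of replicated peaks of higher signal, in which the mean of the immediate early genes was 0.385 (permutation adjusted p = 0.0520).

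The region within 10 kb of Otx2 (ENSMUSG00000021848.16, chromosome 14, 48657677 to 48673819) held 10 replicated peaks that covered 10310 bp, with 15 peaks in the list of replicate 1 and 18 in that of replicate 2. The Hoxa cluster with 10 kb on either side held 2 replicated peaks covering 1019 bp. The region within 10 kb of Foxg1, a regulator of the forebrain, held 0 replicated peaks, 2 pooled peaks, 1 replicate 1 peak and 0 replicate 2 peaks.

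**Figure D4:**
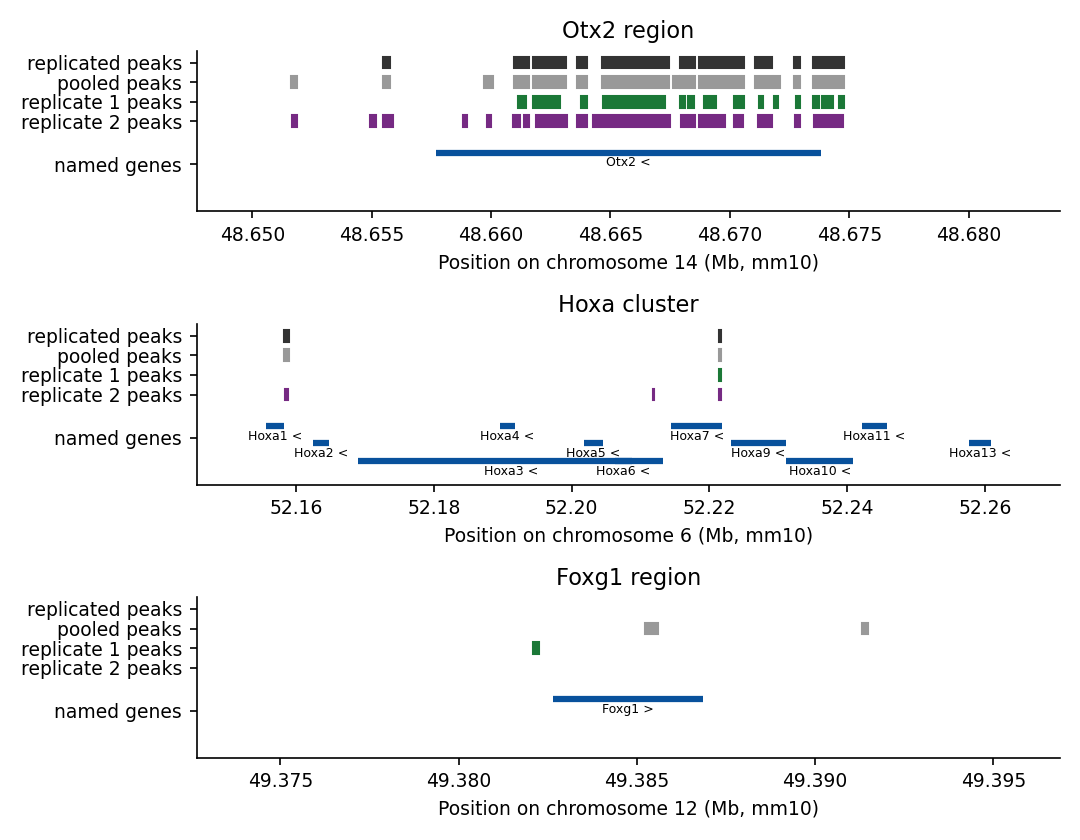
Peaks of the 4 lists (boxes, by list) around Otx2, the Hoxa cluster and Foxg1, with the named genes as blue bars and their strand as an arrow; the x axis is the position in Mb on mm10. The Otx2 region holds 10 replicated peaks, the Hoxa cluster 2 and the Foxg1 region 0.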

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

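The tests of the explanations weighed here were written down before their results were seen, except that the CpG-matched test of replicate 2 alone and the matching on transcript starts were added after the data were seen, and the lists compared in the added peaks of the pooled list were chosen after the result was seen. The limits for reading the tests of weak calls and of CpG-rich promoters were also revised after their values were seen. Both values stayed the same, but the reading of weak calls changed, since its value had met the limit written down beforehand.

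The pooled list held 31057 peaks outside the replicated list, on which the main comparisons rested, with a median signal of 2.49 and a median width of 219 bp, and 17.4% of them were promoter peaks. They overlapped a peak of replicate 1 alone in 4526 cases, of replicate 2 alone in 14877, of both in 184 and of neither in 11470. They marked 623 further genes. Of 14 lists tested, 3 gained a higher share than other unmarked genes (7.57 to 7.62%). These were 7 of the 9 unmarked forebrain regulators, with Tbr1, Dlx1 and Dlx2 (exact adjusted p = 3.26e-06), 4 of 8 unmarked oligodendrocyte lineage genes, Enpp6, Cspg4, Sox10 and Olig2 (0.00863) and 3 of 6 unmarked dopaminergic genes, Lmx1b, Corin and Ddc (0.0262). Odorant receptors gained a lower share, 2 of 1092 (0.183% against 8.80%, exact adjusted p = 3.11e-36). These gains were not compared with CpG-matched lists. The median CpG ratio over all unmarked promoters was 0.180, so a part of CpG in the gains was not accounted for. A further 9 replicated peaks lay on scaffolds outside the main chromosomes.

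The list of replicate 2 was longer than that of replicate 1. Additional weak calls stay open. The 36766 replicate 2 peaks without a partner in replicate 1 had a median percentile of 31.8 by −log10 p within their list (quartiles 15.8 to 46.7). This met what had been written down for weak calls. The 10072 unpaired peaks of replicate 1 also sat low in their list, at 20.8. The lowest value this measure can take rises with the unpaired share of a list, which was larger in replicate 2. The 2 medians can therefore not be compared, and the measure did not decide. More non-neural cells in the pool, microglia and vessel cells included, would place non-neural genes among those marked in replicate 2 alone. The odds ratio of 13.3 (95% interval 6.81 to 25.9, 15 of 36 genes) met what had been written down for it. That ratio favours any list with few genes marked in replicate 1, Hox genes and odorant receptors included, so it did not decide. Among the 84 non-neural genes unmarked in replicate 1, 17.9% were marked in replicate 2, against 12.5% (5.95 to 19.0%) in CpG-matched lists (permutation p = 0.175). That share joins lists on both sides of their matched lists. Germline genes had 0% against 18.9%, microglia and immune genes 26.7% against 8.29% and meningeal and mesenchymal genes 44.4% against 19.4%. None of these passed (permutation adjusted p = 0.224, 0.198 and 0.274). Odorant receptors (0.458% against 3.84%, permutation adjusted p = 0.00024) lay below theirs, and Hox genes had 10.5% against 29.5% (0.0506). More non-neural cells were thus neither shown nor excluded. A difference in depth stays open because read counts were not analysed here. No further biological explanation was tested, as the replicates differ in no labelled condition but the number of embryos.

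Some promoters of non-neural genes carried peaks, 25 of the 105 genes of the 7 non-neural lists. That CpG-rich promoters carry the mark whatever the tissue did not hold for all of these genes. The test did not decide whether it accounts for the marked ones. Of the members with a CpG ratio of 0.5 or more, 12 of 21 were marked. Over all protein-coding genes 92.0% were marked with a ratio from 0.5 to 0.75, and 98.1% above it. The share of all members, 23.8%, lay below the 41.6% of CpG-matched lists (34.3 to 48.6%, permutation p = 2e-05, the smallest the permutations can give). No reading had been written down for that side, and it left no excess of marked genes to account for. Of the 84 other members, 13 were marked, a lower share than among the CpG-rich ones. A part of CpG in which members were marked therefore stays open. For cells of blood, vessels or meninges, 21.7% of the 46 CpG-poor members of those lists were marked (exact 95% interval 10.9 to 36.4%), against 25.6% of other CpG-poor genes (Fisher's exact p = 0.615), an interval too wide to decide. Such cells may be present in the tissue and stay open.

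Midbrain regional regulators, general neuronal, immediate early, neural progenitor and housekeeping genes had wide promoter domains. The CpG ratio within 500 bp of the 5′ end of the gene is argued against as the whole cause. All 5 lists stayed wider than lists matched on it, with a highest permutation adjusted p of 0.0323. That ratio covers neither other starts nor the length of a CpG-rich stretch, so CpG over the whole domain was not tested. More annotated transcript starts per gene are also argued against as the whole cause. All 5 lists stayed wider than lists matched on the number of starts, with a highest permutation adjusted p of 0.0490. Peak calling that splits a broad region into neighbouring peaks was not excluded, since without merging 2 of the 5 lists were wider. A biological difference between gene groups stays open as an untested hypothesis.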

How the results depend on the processing

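The tests without genes that share a promoter, with matching on transcript starts, with CpG matching of signal and with the 50% of higher signal in each replicate list were chosen after the results were seen; the other alternatives were planned. Depth is unknown, so its effect on any count could not be tried. No paired analysis was possible because there was 1 group. Of the values and counts that answer a comparison, 55 of 83 planned and 10 of 12 added recomputations stayed within their error or within 1.5 times, and of those for single lists 425 of 497 and 75 of 85 kept the side of the threshold and any called direction. Among these 34 and 7 changed direction with no call on either side. A list is said to have turned below where the direction changed and a call stood on 1 side at least. Elsewhere, unless said, the cause was not tested.

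At least 50% overlap gave shared shares of 69.7% and 33.1% (replicates 1 and 2), the top 20000 peaks 93.3% and 84.5%, and the 50% of higher signal 95.2% and 54.5%. The correlation was 0.90 with −log10 p and 0.58 away from promoters. The promoter share of peaks was 38.9% to 55.6% without 1 replicate, 40.1% in the pooled list and 90.4% in the 50% of replicated peaks of higher signal.

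With that 50% of peaks, 3 lists were higher and 11 lower for promoter peaks, 1 narrower, 0 higher and 5 lower for signal and 0 higher for distal peaks. It turned the promoter shares of regional regulators (31.8%) and cell cycle genes (50%), and the widths of dopaminergic (1783 bp) and transmitter genes (5425 bp). CpG matching left 1 list higher and 4 lower for promoter peaks and turned the regional regulators (86.4%, below their matched lists), while dopaminergic (66.7%) and astrocyte genes (61.5%) changed direction without a call. The pooled list turned the forebrain regulators (90%) and gave 7 lists higher for distal peaks, and a distal limit of 5 kb gave 1. Without 1 replicate, 6 to 7 lists were narrower (4 of the 7 testable in the list of replicate 2 alone) and 1 to 2 higher for signal. Without merging 2 lists were wider. Gaps of 3 kb left 2 narrower and turned the forebrain regulators (2750 bp) and transmitter genes (2564 bp). Matching on starts left 2 narrower. Leaving out shared promoters left 1 narrower and turned the transmitter genes (2252 bp).

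For replicate 2 alone, 2 of 13 lists tested were higher with intervals of 0.5 kb, 5 of 17 with 2 kb, 7 of 13 with the 50% of higher signal and 1 of 12 with the top 20000 peaks. Of the 6 main calls, 4, 0, 4 and 5 were in lists too small to be tested there, and 1, 5, 2 and 0 held. With the top 20000, cell cycle genes turned (27.8%, and 35% in the 50% of higher signal). For replicate 1 alone, 2 were higher with the top 20000, where transmitter genes turned (20%).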

Other observations

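All the groups and tests of this part were chosen after the results were seen, from a scan of 333 families of genes that share a symbol stem and several further groupings, so the p-values below describe these lists and are not independent evidence.

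Clustered protocadherins, cell surface proteins of which single neurons express different sets, had few marked promoters among their alpha, beta and gamma genes outside the C type. Of these 52 genes 3 were marked, against 73.0% in CpG-matched lists (permutation adjusted p = 0.0004, from the smallest p the permutations can give). The count was 4 with the list of replicate 1 and 11 with that of replicate 2 (21.2% against 76.3% in CpG-matched lists, permutation adjusted p = 0.000533). The alpha genes were marked in 0 of 12 cases, the beta genes in 1 of 22 (Pcdhb16) and the gamma genes in 2 of 18 (Pcdhga2 and Pcdhga11, the former without a peak in replicate 1). With the list of replicate 2 these counts were 0, 5 and 6, and with that of replicate 1 they were 0, 1 and 3. The C-type genes were marked in 4 of 5 cases, namely Pcdhac1, Pcdhac2, Pcdhgc3 and Pcdhgc4, against 79.4% in CpG-matched lists (permutation adjusted p = 1), and Pcdhgc5 was marked in the list of each replicate. Protocadherins outside the clusters were marked in 11 of 12 cases, Pcdh12 being the exception, against 85.1% in CpG-matched lists (permutation adjusted p = 1), with a median domain of 4624 bp (permutation adjusted p = 0.0003).

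Genes of motile cilia, the axonemal dynein heavy chains, radial spoke proteins and cilia- and flagella-associated proteins, were marked in 42 of 54 cases, against 69.4% in CpG-matched lists (permutation adjusted p = 0.194). The count was 8 of 15 for the dynein genes (Dnah), 6 of 8 for the radial spoke genes (Rsph) and 28 of 31 for the Cfap genes, whose higher share by Fisher's exact test (adjusted p = 0.00429) did not hold against CpG-matched lists (permutation adjusted p = 0.155). Domains of the 3 families together were narrow, with a median of 896.5 bp (permutation adjusted p = 0.0003), and the median signal was 6.13 (permutation adjusted p = 0.0006). All 14 intraflagellar transport genes, which serve cilia of any kind, were marked, against 95.7% in CpG-matched lists (permutation adjusted p = 1), with a median domain of 1695 bp (permutation adjusted p = 0.690). The difference between the groups was not tested. Over all 333 families, 97 had a higher and 64 a lower share of marked promoters by Fisher's exact test, and 4 and 10 against CpG-matched lists.

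The widest 1% of promoter domains, 138 genes, held 10 of the 19 marked midbrain regional regulators, 52.6% against 0.929% of other marked genes (Fisher's exact adjusted p = 8.04e-15). It also held 4 of 12 transmitter identity genes, Slc17a6, Gad2, Slc32a1 and Gad1 (exact adjusted p = 2.90e-05), 3 of 20 general neuronal genes, Myt1l, Celf4 and Elavl2 (0.00427) and 2 of 11 forebrain regulators, Bcl11b and Lhx2 (0.0167). Within that 1%, the 10 regional regulators had a median signal of 6.22 against 14.8 (9.80 to 18.6) in random lists from it (permutation p = 6e-05). Tfap2d with 4.55, Barhl1 with 4.92, Gata3 with 4.96 and Otx2 with 5.45 had domains that were broad after merging and low at once. This breadth rests on peaks merged across gaps of up to 1 kb. Without merging, the width call of the regional regulators ended.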
